A study of Mus musculus with 10 samples.

How the data were processed

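Dams of the restricted group received 50% of their previous food from day 1.5 to day 11.5 of pregnancy, and placentas of both groups were taken on day 18.5, per the labels. Total RNA was pooled from 2 placentas per dam, labelled with Cy3 and hybridised to Agilent 4-array slides of design 026655, per the labels and the file headers. Of the 10 samples 5 were control and 5 restricted, as the maternal treatment label gives. The intensity values per spot were made by Agilent Feature Extraction 9.5.3.1, per the file headers, which subtracts background to give a processed signal and marks spots that are outliers, saturated or well above background. The deposited value table is a ratio: the authors' values equal each array's processed signal divided by its 75th percentile over probes, as found by setting each column against the scanner values (correlation of at least 0.9998; column medians from 0.08 to 0.13); it was used as an alternative. The deposited flags for background and outliers, which are other values per spot, were used as given.

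From these files, log2 processed signal minus each array's 75th percentile over non-control spots was computed. The 75th percentile ran from 127.7 to 271.7 intensity units. Outlier spots were left out, spots of a probe were averaged, and a probe was kept where it was well above background on at least 4 of the 5 arrays of a group, which left 16218 probes. The probe with the highest mean stood for a gene with several, and a probe with no symbol stood for itself. That gave 13367 genes, 11752 with a symbol, with 15 missing values. Of 2457 genes with several kept probes, 2 had probes that went opposite ways, each at an unadjusted p under 0.05. Symbols were brought up to date through a RefSeq table of assembly GRCm38.p6, used for names only: 26055 of 39429 probes matched by their accession, 105 by another accession, 3126 by symbol and 910 by synonym, 2094 kept the file's name and 7139 had no symbol. Probe coordinates are those of the files, on mm9.

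Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Gene lists (39, each with at least 5 tested members) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Distances between arrays were tested by exact permutation. The samples, tests, gene lists and the settings listed first in the last paragraph were fixed before the data were examined. Genes named in the text are the 10 with the smallest unadjusted p in each direction, since none passed, up to 3 members per described list and the genes of a fixed focus list. Which 19 lists are described was chosen after their values were seen: the 6 that passed at the preset correlation, and others on placental tissues, transport, growth and neighbouring cells. The 20 others are summarised. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

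The arrays lay on 3 slides: 4 control arrays on slide 1, 1 control and 3 restricted arrays on slide 2, and 2 restricted arrays on slide 3. Slide and group therefore overlap, and a fit with slide as a block takes the difference from slide 2 alone. No pair among the 45 pairs of arrays held identical values, and correlations ran from 0.965 to 0.990. The fit was tested on simulated data for the comparison of restricted with control placentas: with 200 of 13367 genes changed, it recovered 44.8% of 1.5-fold, 88.1% of 2-fold and 95.5% of 3-fold changes, with 8 calls among unchanged genes. With 5 lists shifted by 0.2 log2, 4 were recovered and 0 others were called; simulated genes vary independently, unlike the real ones.

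Alternatives were another background correction and normalization, quantile and median scaling, the deposited value table, no filter and a stricter filter, other rules for several probes, another variance prior, array weights, slide and Y-linked signal in the model, dams numbered under 200 against those from 200 as a block (a split of the dam numbers, which the labels do not describe as cohorts), and each dam left out. The other background correction was normexp with an offset of 50 intensity units, followed by quantile normalization. That offset makes log2 differences of dim genes smaller by arithmetic. The Y-linked signal is the mean log2 of Ddx3y, Eif2s3y, Kdm5d and Uty, of which the last 2 were not well above background in any pool. Alternatives added after the data were seen were the 75th percentile over detected probes, slide as a random block, the slide with both groups alone, and yolk sac signal, Y-linked and Xist signal, or the signal of the 2 detected Y-linked genes as covariates.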

Results

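Placental gene expression was measured near the end of mouse pregnancy in 5 dams fed freely throughout (control) and 5 dams given 50% of their previous food intake from the start of pregnancy to its middle and then fed freely again (restricted). Each sample was RNA from the placentas of 1 dam, 2 placentas per pool, hybridised to a 1-colour whole-genome oligonucleotide array, so the replicate was the dam. Samples are named here by group and dam number. The arrays carried 39429 probes. Between 40.8% and 47.1% of the spots of an array were well above background, no spot was saturated, and 13367 genes measured in at least 4 dams of a group were tested. The number of arrays limits the precision. The comparison asks whether a placenta still differed from that of a freely fed dam a week after food was restored.

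Late in pregnancy no gene differed between restricted and control placentas past the threshold. The smallest Benjamini-Hochberg adjusted p from limma was 0.352, with 0 genes higher and 0 genes lower, and 818 genes (6.12% of those tested) had an unadjusted p under 0.05, where chance gives 668. Of these 818 genes 518 were higher in the restricted group and 300 lower. In this fit, which leaves out slide, the 95% interval of the restricted minus control difference lay within a 2-fold change in either direction for 95.6% of genes and within 1.5-fold for 80.2%. The share within 2-fold was 81.1% with slide as a block and 77.5% without the filter on dim probes. The differences with and without the slide block correlated at 0.55 across genes, which are not independent replicates. Both fits use the arrays of slide 2, so a correlation arises without any effect of diet. The 0.55 therefore does not show that the fits give the same result. The median SD between dams was 0.192 on the log2 scale in control and 0.175 in restricted placentas (n = 5 each). With slide as a block, which rests on the 1 control and 3 restricted arrays of the slide that held both groups, 0 genes passed and 547 had an unadjusted p under 0.05. With each probe tested on its own, 1 probe passed, for Abi2, a component of the actin-regulating WAVE complex (log2 difference 0.78, adjusted p = 0.0176 from limma), which was named after its value was seen. The brightest probe of Abi2, which stands for the gene elsewhere, had a log2 difference of 0.12 (adjusted p = 0.852).

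The genes with the smallest unadjusted p are given as values, because none of them passed. Among those higher in the restricted group, Xpo4, a nuclear export receptor (probe at chromosome 14, 58201110 to 58201169, mm9), had a log2 signal of -2.32 ± 0.14 (SD, n = 5) against -2.96 ± 0.18 in controls, a fold of 1.57 with a 95% interval of 1.34 to 1.84. Its probe was well above background on 2 of 5 control and 4 of 5 restricted arrays, so the control level is near the limit of measurement, and under normexp background correction with quantile normalization its log2 difference was 0.12 against 0.65. Itgam, the CD11b integrin chain of myeloid cells (chromosome 7, 135261755 to 135261814), had a fold of 1.59 (1.32 to 1.92). Fgf23, a hormone that lowers phosphate (chromosome 6, 127030758 to 127030817), had a fold of 1.60 (1.31 to 1.95), and Idua, a lysosomal enzyme that degrades glycosaminoglycans, 1.51 (1.26 to 1.82). The remaining 6 of the 10 were Gm33989 (2.02-fold), Zfp872 (1.89-fold), Pdzrn3 (1.64-fold), Gm831 (1.60-fold), Krt222 (1.54-fold) and the homeobox gene Lhx6 (1.39-fold). Gm831 was well above background on 3 of 5 control arrays. All 10 had an adjusted p of 0.352. Itgam, Fgf23, Idua, Krt222, Pdzrn3 and Lhx6 moved together over the control pools, highest in control 245 and lowest in control 249 and 262. They are therefore not independent results. With the Y-linked signal of the pools as a covariate, Zfp872 alone passed, at a log2 difference of 1.37 and an adjusted p of 0.0429 from limma. With only the 2 Y-linked genes that were detected as the covariate 6 genes passed, all higher, among them Zfp872 (1.19) and Gm33989 (1.29), both at an adjusted p of 0.028; the others were Pitpnm2os1 and 3 probes without a symbol.

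Among genes lower in the restricted group, Cfp, which encodes the complement factor properdin (chromosome X, 20502742 to 20502801, mm9), had a log2 signal of -1.16 ± 0.25 (SD, n = 5) against -0.44 ± 0.13, a ratio of 0.606 with a 95% interval of 0.503 to 0.729. Cd99, a cell surface glycoprotein, had a ratio of 0.648 (0.537 to 0.782), and Gpx2, a glutathione peroxidase, 0.743 (0.649 to 0.850). Corin, a protease that activates natriuretic peptides, had a ratio of 0.728 (0.615 to 0.862). The other 6 were Krtdap (0.523), C1qtnf5 (0.605), Vpreb1 (0.658), Nrn1l (0.673), B9d1 (0.687) and Ptk7 (0.790). C1qtnf5 and Vpreb1 were each well above background on 4 of 5 restricted arrays, so their restricted level is near the limit of measurement. Adjusted p-values from limma for these 10 genes ran from 0.352 to 0.548. Under normexp with quantile normalization the 20 genes of both directions kept their sign, and 16 of them had a log2 difference over 1.5 times smaller. The offset of 50 intensity units in that setting makes log2 differences of dim genes smaller by arithmetic, so part of this shrinkage comes from the setting itself. With slide as a block the 20 genes kept their sign too, and Cfp (-0.44), Gpx2 (-0.24) and Nrn1l (-0.26) were over 1.5 times smaller and Krtdap (-1.73) larger. Those values compare control 264 with 3 restricted arrays, all among the arrays by which the genes had been picked. The kept signs therefore follow largely from that selection and do not test slide.

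**Figure D1:**
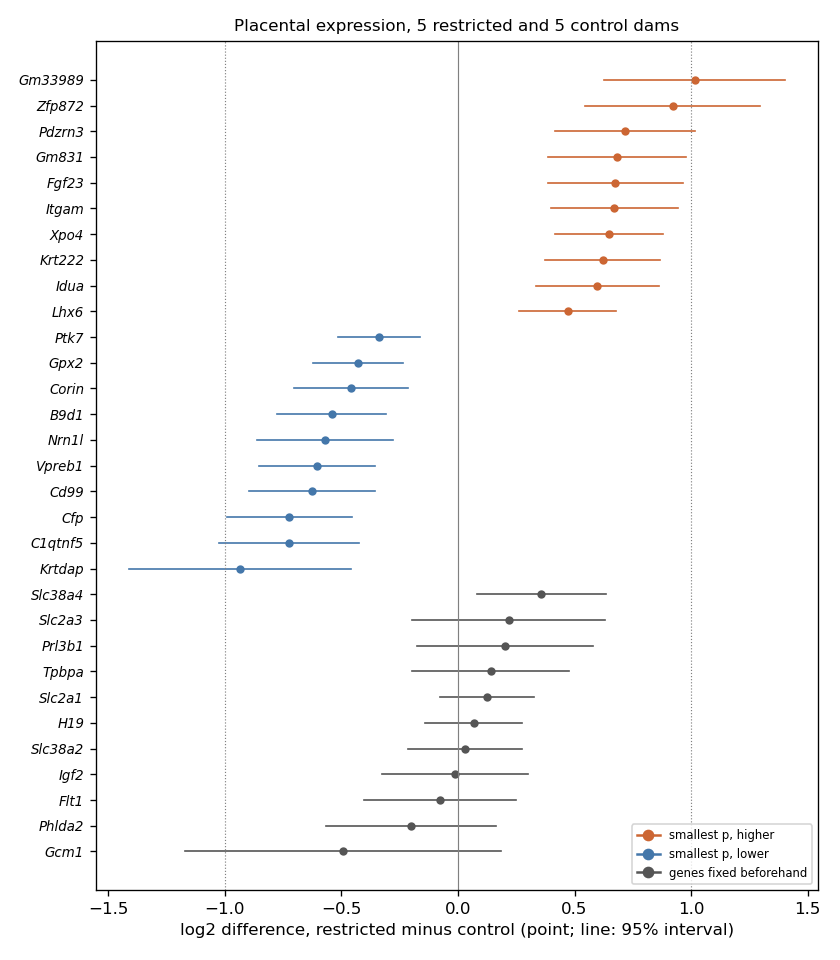
Log2 difference in placental signal, restricted minus control, for the 10 genes with the smallest unadjusted p in each direction and the genes fixed beforehand; points are estimates from 5 dams per group, lines are 95% intervals, and dotted lines mark a 2-fold change. No gene shown passed the adjusted threshold, and Xpo4 has the smallest unadjusted p, at a log2 difference of 0.65.

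Genes of placental nutrient supply and growth that were fixed beforehand did not pass either. Slc2a1 and Slc2a3, glucose transporters, had log2 differences of 0.12 (SE 0.09) and 0.22 (SE 0.19). Of the sodium-coupled amino acid transporters, Slc38a2 differed by 0.03 (SE 0.11) and Slc38a4 by 0.36 (SE 0.13), the latter with an unadjusted p of 0.0158 and an adjusted p of 0.762 from limma, and 0.12 with slide as a block. The imprinted growth factor Igf2 differed by -0.01 (SE 0.14), the imprinted RNA H19 by 0.07 (SE 0.10) and Phlda2, an imprinted gene that restrains placental growth, by -0.20 (SE 0.17). The spongiotrophoblast marker Tpbpa differed by 0.14 (SE 0.15) and the placental lactogen Prl3b1 by 0.20 (SE 0.17). With slide as a block Prl3b1 was 0.49, Tpbpa 0.32, Phlda2 -0.45, Slc2a3 0.07 and Gcm1 -0.27, and under normexp with quantile normalization Phlda2 was -0.12 and Gcm1 -0.13, with Prl3b1 at 0. Quantile normalization gives all arrays the same values rank by rank, which narrows differences among the brightest signals. Prl3b1 was the brightest of these genes (mean log2 signal 10.35 in control and 10.55 in restricted), so its 0 does not show that a difference was absent. Gcm1, a regulator of labyrinth trophoblast, differed by -0.49 (SE 0.31) and Flt1, a VEGF receptor, by -0.08 (SE 0.15). Signs were not stable for 6 of these genes: H19 turned under both quantile settings and with slide as a block, Igf2 under median scaling and without any 1 of control 245, 249 or 264 or restricted 253, Slc38a2 with array weights, with yolk sac signal as a covariate and without control 172 or restricted 267, Flt1 without restricted 164, and Gcm1 (0.115) and Slc2a3 (-0.031) with Y-linked signal as a covariate. Hsd11b2, which inactivates glucocorticoids, was not tested because its probes were not well above background in enough arrays.

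As groups, 6 of 39 gene lists lay higher in the restricted placentas than the other genes when the correlation between genes was preset at 0.01 (limma camera), and none did when it was estimated. Lists can share members: Prl7d1 and Prl3a1 are in both the prolactin family and the spongiotrophoblast list, so the calls for those lists are not separate results. The unfolded protein response list had 19 of 20 tested members with a higher mean (median log2 difference 0.22, adjusted p = 2.54e-05, and adjusted p = 0.796 with an estimated correlation). The prolactin family, hormones made by trophoblast, had 18 of 20 (median 0.24, adjusted p = 0.00192, and 0.796 as the adjusted p with an estimated correlation). The pregnancy-specific glycoproteins had 17 of 19 (median 0.24, adjusted p = 0.00254, and 0.796 as the adjusted p with an estimated correlation). Erythroid genes had 13 of 15 (median 0.38, adjusted p = 0.00699, and 0.816 as the adjusted p with an estimated correlation). Amino acid transporters had 17 of 20 (median 0.15, adjusted p = 0.00809, and 0.796 as the adjusted p with an estimated correlation), and spongiotrophoblast genes 14 of 18 (median 0.23, adjusted p = 0.0204, and 0.796 as the adjusted p with an estimated correlation). The fry test called 0 lists, with a smallest adjusted p of 0.706. No member of these 6 lists passed, over all genes or adjusted over the list alone. Random regroupings of the 10 samples gave 6 or more lists in 50 of 100 splits, the real one included.

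Members of these lists are given as values. In the unfolded protein response list, Herpud1, a factor in the disposal of misfolded proteins, differed by 0.65 (SE 0.19), the chaperone Hsp90b1 by 0.36 (SE 0.17) and Dnajc3 by 0.20 (SE 0.09). In the prolactin family, Prl7b1 differed by 0.40 (SE 0.18), Prl3a1 by 0.32 (SE 0.15) and Prl7d1 by 0.18 (SE 0.08). Psg20 and Psg18 differed by 0.50 (SE 0.25) and 0.30 (SE 0.15). The globin genes Hbb-bt, Hbb-b2 and Hba-a2 differed by 0.52 (SE 0.21), 0.54 (SE 0.24) and 0.41 (SE 0.20). Among amino acid transporters, Slc6a20a differed by 0.43 (SE 0.13) and Slc36a1, well above background on 3 of 5 control arrays, by 0.61 (SE 0.22). Under normexp with quantile normalization several of these were over 1.5 times smaller, at 0.29 for Hbb-bt, 0.22 for Hbb-b2, 0.12 for Hba-a2, 0.09 for Psg18, 0.20 for Slc36a1 and 0.005 for Dnajc3, and the erythroid median was 0.21. Under quantile normalization alone Hbb-bt was 0.32, Hbb-b2 0.16, Hba-a2 0.24 and Psg18 0.11. These genes had mean log2 signals from 8.33 to 9.28 in control, and quantile normalization narrows differences among the brightest signals. With slide as a block Herpud1 was 0.38, Dnajc3 0.44 and Hba-a2 0.67. With slide as a block, and so within the slide that held both groups, the medians were 0.26 for the unfolded protein response, 0.31 for the prolactin family, 0.31 for the pregnancy-specific glycoproteins, 0.52 for erythroid genes, 0.12 for amino acid transport and 0.29 for spongiotrophoblast, and the last 2 no longer passed (adjusted p = 0.102 and 0.125, camera). With the Y-linked signal of the pools as a covariate the unfolded protein response, amino acid transport and spongiotrophoblast lists did not pass (adjusted p = 0.0603, 0.482 and 0.0603, camera), with medians of 0.17, 0.03 and 0.28, and with only the 2 detected Y-linked genes as the covariate amino acid transport alone did not (median 0.07, adjusted p = 0.214). Quantile normalization ended the call for the pregnancy-specific glycoproteins (median 0.11, adjusted p = 0.144) and for spongiotrophoblast (0.26), as did normexp with quantile normalization (adjusted p = 0.126 and 0.183). Array weights ended that for amino acid transport (adjusted p = 0.102), and Y-linked with Xist signal as covariates left the pregnancy-specific glycoproteins and erythroid genes as the called ones of the 6, with the prolactin family at an adjusted p of 0.0506. Restricted 267, the pool that stood apart in yolk sac genes, had the highest score of the 10 pools in all 6 lists. On leaving out 1 dam, calls ended for erythroid genes without restricted 267 (median 0.21, adjusted p = 0.172), restricted 253 (0.0623) or control 264 (0.159), for amino acid transport without restricted 267 (0.053) or control 172 (0.189), with a median of 0.08 but no lost call without control 249, and for the pregnancy-specific glycoproteins without control 245 (0.0518). The spongiotrophoblast call ended without any 1 of control 245, 249 or 264 or restricted 240, 253 or 267 (adjusted p from 0.0519 to 0.167), with medians of 0.14 without restricted 267 and 0.15 without control 245. The pools of the groups did not overlap in score for 1 of 39 lists, amino acid transport, where control pools lay between -0.197 and -0.005 and restricted pools between 0.031 and 0.145. For a list chosen in advance 0.794% of splits separate the groups in this way. Amino acid transport is singled out here as the 1 of 39 that did so, so that share is not a p-value for it.

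**Figure D2:**
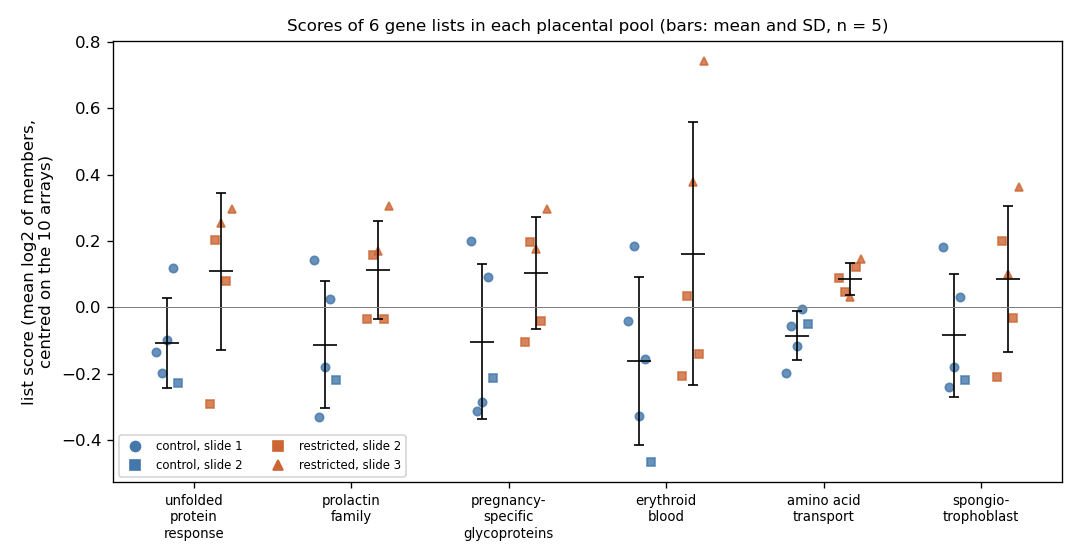
Score of 6 gene lists in each of the 10 placental pools: the mean log2 signal of the members, centred on all arrays, with black bars for the mean and SD of 5 dams. Colours separate control and restricted dams and symbols the slides; the pools of the groups overlap in 5 of the lists and not in amino acid transport, and no list passed with an estimated correlation between genes.

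The other lists described here did not pass. Glycogen trophoblast genes had a median log2 difference of 0.13 (adjusted p = 0.168, camera), other trophoblast giant cells 0.11 (0.130), labyrinth syncytiotrophoblast 0.15 (0.469; -0.06 without restricted 267), glucose and lactate transport 0.12 (0.226), lipid transport 0.004 (0.653), ion and micronutrient transport 0.023 (0.890), imprinted genes -0.006 (0.469) and insulin, IGF and mTOR signalling 0.001 (0.883). The medians near zero for lipid transport, ion transport, imprinted genes and insulin signalling changed sign between scalings or settings. Cell cycle genes had a median of -0.08 (0.204) and steroid hormone metabolism -0.09 (0.204). The steroid hormone list passed with slide as a block, at a median of -0.28 (adjusted p = 0.0209, and adjusted p = 0.47 with an estimated correlation), a value that rests on 1 control array. Among single members, Pltp, a phospholipid transfer protein, differed by 0.43 (SE 0.13; 0.17 with slide as a block), and Trpv6, a calcium channel, and S100g, a calcium-binding protein, each by -0.33 (SE 0.11 and 0.13). Macrophage genes had a median of -0.18 (0.168), with 14 of 19 members lower, and passed without the filter on dim probes (-0.17, adjusted p = 0.00222) and under median scaling (-0.14, 0.0439), with adjusted p from 0.00222 to 0.938 over all alternatives. With an estimated correlation the adjusted p of these calls was 0.728 and 0.968. Itgam, one of the 5 that were higher, was the single member of any list to pass when adjusted over the list alone. The 20 lists not described had medians from -0.09 to 0.13 and a smallest adjusted p of 0.168. Under alternatives 8 of them passed at least once at the preset correlation and 0 with an estimated one (smallest adjusted p 0.359). Those past the threshold with slide as a block were pericytes, stroma and smooth muscle (median -0.63, adjusted p = 1.95e-06), extracellular matrix (-0.20, 0.0339), glucocorticoid targets (-0.12, 0.0131) and oxidative phosphorylation (-0.07, 0.0131), on 1 control array. Pericytes, stroma and smooth muscle also passed with each of the 3 covariates of fetal sex (medians from -0.47 to -0.33).

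Pools differed in genes of tissues next to the placenta, whatever the group. The 24 yolk sac endoderm genes, among them Afp and the apolipoproteins, had a median of -3.52 in restricted 267, on the log2 scale against the median of the other arrays, with 21 of 24 members lower by more than 1. In control 172 the median was 1.44, with 19 members higher by more than 1. Apoa1 was 0.06 in restricted 267 and 4.55 to 5.93 in the other restricted pools. The list median between groups was -0.26 (adjusted p = 0.226, camera), and 0.36 without restricted 267 (adjusted p = 0.0451). The list passed with a lower median without control 249 (-0.63, adjusted p = 0.0201), control 262 (-0.41, 0.0464) or restricted 164 (-0.53, 0.0342), and over all alternatives the adjusted p ran from 0.00833 to 0.858. These calls rest on the preset correlation. Of the 39 list calls made under an alternative only, over all lists, 0 passed with an estimated correlation (smallest adjusted p 0.359), and the adjusted p for the yolk sac list was 0.895 without restricted 267 and 0.989, 0.837 and 0.826 without control 249, control 262 and restricted 164. Uterine natural killer genes, such as the granzymes Gzmd and Gzmg, had a median of -0.31 (adjusted p = 0.479), and -1.76 with slide as a block (adjusted p = 4.99e-06, and adjusted p = 0.642 with an estimated correlation), a value that rests on 1 control array. Markers of fetal sex differed between pools as well. The Y-linked gene Ddx3y was not well above background in 2 of 5 control and 0 of 5 restricted pools, Eif2s3y was not in 2 of 5 of either group, and Kdm5d and Uty were not in any pool. Xist, which is transcribed from the inactive X chromosome of females, was well above background in 5 of 5 control and 2 of 5 restricted pools. Neither Ddx3y nor Eif2s3y was well above background in control 172 or control 245, and Xist was not in restricted 164, 253 or 267. The markers of fetal sex were therefore not balanced between the groups.

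**Figure D3:**
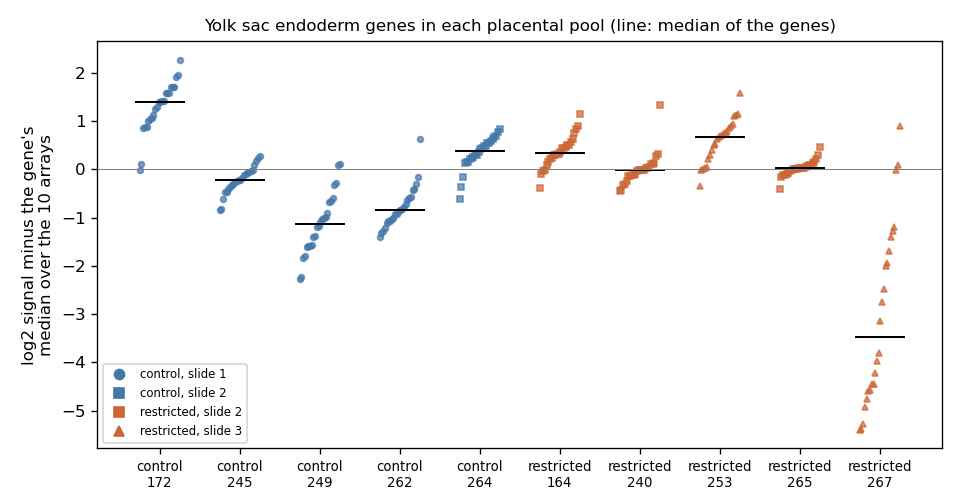
Log2 signal of 24 yolk sac endoderm genes in each placental pool, minus the gene's median over the 10 arrays; each point is 1 gene, black lines are medians, colours mark the groups and symbols the slides. Restricted 267 lies far below the other pools, with Apoa1 at 0.06 before centring against 4.55 or more in the other restricted pools.

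On the whole profile no separation of the groups was detected. The mean distance between arrays of different groups exceeded that between arrays of one group by 0.20 (exact permutation p = 0.349, one-sided, 252 splits, smallest possible 0.00794). Distances within the restricted group averaged 47.1 and within the control group 48.3, a difference of -1.14 (exact permutation p = 0.667, two-sided). Without the filter on dim probes that difference was -31.2 (exact permutation p = 0.0238). More probes enter the distance in that setting, many of them near background, so its size cannot be set against -1.14. The first principal component held 26.0% of the variance, and 13 of the 50 genes that weighed most on it were yolk sac genes. Over the pools this component correlated with the yolk sac score at r = -0.97.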

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

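The tests of a poor array and of maternal diet in this part were chosen after the result was seen, and that of neighbouring spots was added after the pattern was seen, with its limits set before it was run. Within each group of 5 dams, the gap between the farthest dam and its nearest neighbour was set against the range. Of 194 such groups of values 10 exceeded the critical value of 0.71, where 9.7 would be expected by chance. The groups are not independent, since lists were tested beside their own members, so the count can vary widely around that number. Some genes had also been picked for a small p. A count near 9.7 therefore does not show that the far values arose by chance.

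Of these far values 5 of 10 came from restricted 267. They were the yolk sac list (gap 0.835 of the range; score -2.78 against 0.25 to 0.85), Apoa1 (0.766) and the fibrinogen gene Fga (0.758; -4.82 against 0.46 to 2.15), the labyrinth syncytiotrophoblast list (0.783; 0.62 against -0.19 to -0.02) and Ptk7 (0.775). In control 172, B9d1 (0.805) and Flt1 (0.767; 2.57 against 2.97 to 3.09) stood apart. The others were Slc36a1 in control 245 (0.788), Lifr in restricted 164 (0.807) and Rbp4 in restricted 240 (0.806). Fga was well above background on 4 of 5 restricted arrays and Slc36a1 on 3 of 5 control arrays, so their gaps include values near the limit of measurement.

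The low yolk sac signal of restricted 267 was weighed further. The tables argue against a fault of the array as the cause of the low yolk sac signal: 42.2% of its spots were well above background, within the range of the other arrays, and of 118 probes beside the yolk sac spots 1.7% were lower by more than 1 on the log2 scale. The same array also held 6 of the 10 single probes that fell far from tightly grouped other arrays, which these tests leave unexplained. Less yolk sac tissue in that pool is a candidate explanation: of the 50 genes outside the list that best followed the list's score over the other 9 arrays, 78% were lower in restricted 267 by more than 1 on the log2 scale, just above the 75% set in advance, against 1.25% of all other genes. Maternal diet stays open: the other 4 restricted pools were higher than the 5 control pools, 0.50 against 0.15, opposite to the low signal, but the difference of 0.35 was within the spread (exact permutation p = 0.508, two-sided).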

How the results depend on the processing

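The alternatives named as added were chosen after the data were seen: the percentile over detected probes, slide as a random block, the slide with both groups alone, and the covariates of yolk sac signal, of Y-linked with Xist signal and of the 2 detected Y-linked genes. No gene passed under any alternative at the threshold of 0.05 except 1 higher gene with each probe on its own (Abi2), 1 higher gene with Y-linked signal as a covariate (Zfp872) and 6 higher genes with the detected Y-linked genes as a covariate (Zfp872 and Gm33989 among them). The causes of the changes given here were not tested. The planned block on scan date was not run because all arrays share one date, and distances have no value with a covariate, block, weight or other variance prior. Only 40.8% to 47.1% of an array's spots were well above background, which limits what can be said of dim genes.

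Genes at an unadjusted p under 0.05 numbered 409 under median scaling, with 75.8% higher against 63.3% in the main setting. The lists past the threshold numbered 10 with slide as a block, 12 on the slide with both groups, 3 with Y-linked and Xist signal as covariates, and 0 with an estimated correlation and 0 by fry; leaving out 1 dam gave 4 to 10 (10 without control 262 or restricted 164). Members passing over their list alone numbered 1 in the main setting, 2 under normexp with quantile normalization, without the filter, with Y-linked, with yolk sac, or with Y-linked and Xist signal as covariates, 9 with slide as a block and 13 on the slide with both groups; leaving out 1 dam gave 1 to 13 (13 without restricted 164, 9 without control 262, 5 without control 172, 3 without restricted 253, and 2 without control 264, restricted 265 or restricted 267). The distance between groups was -0.70 under median scaling and -0.05 without the filter, and -0.51 to 0.88 on leaving out 1 dam. The spread difference was -31.2 without the filter, where more and dimmer probes enter the distance, and -6.95 to 3.1 on leaving out 1 dam.

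Of 551 list medians under alternatives 48 changed sign, 29 lost a call and 20 gained one (1 of them with its sign turned, yolk sac without restricted 267), and of 2176 values of named genes 32 changed sign and 3 gained a call. The 6 called lists had medians above 0 in each of 29 alternative settings with the preset correlation, and passed in 17 of them for spongiotrophoblast, 21 for amino acid transport, 26 for erythroid genes and for pregnancy-specific glycoproteins, 27 for the unfolded protein response and 28 for the prolactin family. The lists not described gained 19 calls under alternatives, of 8 lists: 4 each with slide as a block and on the slide with both groups, 3 without control 172 (angiogenesis, endothelium, extracellular matrix), 1 each without control 262 and restricted 164 (both hypoxia and glycolysis) and restricted 240 (cathepsins), 1 each with array weights and yolk sac signal (both angiogenesis), and 1 with each of the 3 covariates of fetal sex. With an estimated correlation 0 lists passed in any of the settings where it was run. At the preset correlation, steroid hormone genes passed with slide as a block and on the slide with both groups (median -0.277 in both, adjusted p = 0.0209 and 0.00833), the yolk sac list under median scaling (-0.220, 0.00853) and on the slide with both groups (-0.269, 0.00833), and giant cells with each probe on its own (0.159, 0.0248). Calls were gained on leaving out 1 dam for giant cells without control 262, restricted 164 or restricted 240, for macrophages without control 262 or restricted 240, for glycogen trophoblast without restricted 164 (adjusted p = 0.0392) and for uterine natural killer genes without control 245 (median -0.579, adjusted p = 0.0301). The insulin and mTOR median was -0.014 under normexp, -0.003 under quantile normalization, -0.009 with the deposited values, -0.012 without the filter, -0.008 with the mean of probes, 0 with each probe on its own, -0.025 with array weights, -0.087 with slide as a block and on the slide with both groups, -0.014 with slide as a random block, -0.082 with Y-linked signal, -0.084 with Xist too, -0.076 with the detected Y-linked genes, -0.012 with yolk sac signal, and -0.044 to 0.033 on leaving out 1 dam. The ion transport median was -0.004 under normexp, -0.010 with the mean of probes, -0.021 with array weights, -0.038 with slide as a block and on the slide with both groups, -0.113 with Y-linked signal, -0.097 with Xist too, -0.058 with the detected Y-linked genes, and -0.030 to 0.066 on leaving out 1 dam. The lipid transport median was -0.004 under quantile normalization, -0.005 with the deposited values, -0.028 with Y-linked signal, -0.002 with Xist too, and -0.001 to 0.057 on leaving out 1 dam. The yolk sac median was 0.139 with array weights, 0.680 with Y-linked signal, 0.693 with Xist too, 0.231 with the detected Y-linked genes, 0.042 with its own signal as covariate, and -0.633 to 0.360 on leaving out 1 dam. The imprinted median was 0.039 under median scaling and -0.057 to 0.022 on leaving out 1 dam, the labyrinth median -0.056 to 0.194 on leaving out 1 dam, the cell cycle median 0.020 and the uterine natural killer median 0.077 without the filter, the glucose transport median 0 with Y-linked signal, and the macrophage median 0.006 with Y-linked and Xist signal.

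With Y-linked signal as a covariate Apoa1 was 0.272, Fga 0.182, Gcm1 0.115, Rbp4 0.004, Slc16a4 -0.012 and Slc2a3 -0.031; with Xist too Apoa1 was 0.333, Fga 0.244, Gcm1 0.054 and Slc2a3 -0.021. With slide as a block, and on the slide with both groups, H19 was -0.005, Prl3d1 -0.162, Rbp4 0.046 and Tyrobp 0.034. H19 was -0.123 under normexp and -0.089 under quantile normalization, Igf2 0.032 under median scaling, and Slc38a2 -0.020 with array weights and -0.004 with yolk sac signal. On leaving out 1 dam Slc38a2 ran from -0.038 to 0.072, Igf2 from -0.130 to 0.071, Flt1 from -0.172 to 0.022, Apoa1 from -1.32 to 0.146 and Fga from -1.50 to 0.246, with the signs of Apoa1 and Fga turning without restricted 267.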

Other observations

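The tests of slide in this part were chosen after the result was seen. Probes for 3 genes were well above background in every array of one group and none of the other, and none passed. Dao, a D-amino acid oxidase, was at least 1.97-fold brighter in restricted pools (adjusted p = 0.548, limma), and Ablim2 and Catsper4 at least 1.32-fold and 1.40-fold brighter in control pools (both 0.731). The dim side was set to the lowest signal well above background on each array, or to the probe's own signal where higher.

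Among 15127 probes well above background on at least 9 arrays, 10 lay more than 3 on the log2 scale from the median of the other 9 arrays while those ranged over less than 1.5; 9 of the 10 were lower. In restricted 267 these were Gtf2e1 (-4.97), Dhrsx (-4.68), Ubqln2 (-4.35), Gm6748 (-4.13), Speer5-ps1 (-3.84) and Ap5m1 (-3.66). The others were Fam160a2 in restricted 164 (-3.46), Acot1 in restricted 265 (-3.45), and in control 262 an unnamed probe (-3.21) and Unc93a2 (4.99).

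The 6 lists that lay higher in the restricted group with the preset correlation were set against other groupings of the 10 samples. In 50 of 100 splits, out of 126 possible, 6 or more lists passed, and another split gave 16, so chance is not excluded. With the yolk sac score as a covariate 6 of the 6 lists still passed at the preset correlation. With an estimated correlation 0 lists did (smallest adjusted p 0.748, camera). Without restricted 267, the pool lowest in yolk sac genes, 3 of the 6 passed at the preset correlation. Calls at that correlation are also frequent in other groupings, so a share of yolk sac in the pools stays undecided as a cause. Slide cannot be told apart from the group for these lists: with slide as a block 4 of the 6 passed, on 1 control array. The 3 other splits that kept the 4 arrays of slide 1 together gave at most 1 list. Those 4 arrays were all control, so each such split stays near the real grouping and cannot tell slide from diet. Fetal sex was not excluded either. With Y-linked signal as a covariate 3 of the 6 lists passed, with Y-linked and Xist signal 2, and with the 2 detected Y-linked genes 5.

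The 818 genes at an unadjusted p under 0.05 were likewise matched in 23 of 100 splits, so chance is not excluded, and the highest other split gave 2036. Among 3 other splits that kept the 4 arrays of slide 1 together, the highest gave 1223 genes. Slide alone, in a fit without diet, gave 1880 genes, and with slide as a block the count for diet was 547. The 1880 come from a joint test of 3 slides and the other counts from a test of 1 difference, so their sizes do not measure slide against diet. Slide and diet cannot be told apart here, because 1 slide alone held both groups. For the 0 genes past the adjusted threshold the splits decide nothing, because each of 100 of 100 necessarily gives 0 or more; 4 other splits gave 1 or more, and the highest gave 10.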
